A study of Ovis aries with 4 samples.

How the data were processed

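Ovaries of black sheep were studied at 2 ages, with an m6A immunoprecipitate and an input at each. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with a stranded total RNA kit and sequenced on an Illumina NovaSeq instrument. Samples were grouped by the age and antibody labels. The labels number the young sample as replicate 1 and the aged sample as replicate 2. Whether a sample pooled several animals, and the aligner, the peak caller and the genome build, are not given in the sources used here. The submitters' processing notes name ChIPseeker, which annotates peaks, and DESeq2, which the authors list without a stated role.

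The deposited files hold 1 row per peak, with coordinates, a feature label and a gene. Per the file headers, the authors give a p-value and an adjusted p-value for each peak. Per the file headers, the authors also give a fold enrichment, a linear ratio. The deposited log10 p and log10 adjusted p columns were treated as a score. Every deposited peak had a fold of at least 1.5 and a p-value of at most 0.049, and the deposited lists held no peak weaker than that. All of these were used to describe, rank or filter peaks. Some uses spanned both lists: the common fold cut, the ranking of overlapping peaks by the lower fold, and common classes of the deposited log10 p. Sequencing depth was not given, so whether equal values mean the same in both lists is unknown. Starts were shifted by 1 base to count from 1.

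Genes were named as the deposited files name them. A table of sheep genes of assembly ARS-UI_Ramb_v3.0 was matched by gene identifier, for 99.5% of young peaks, and gave chromosome numbers, gene lengths and gene ends. The build of the files is not named, so the table's coordinates are not printed. Its gene ends were compared with peak boundaries because they coincided to the base on 27 chromosomes in both lists. Exon positions and genome sequence were not used here, so sequence motifs, an independent annotation and peaks moved at random within genes were not run.

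A peak was a distinct chromosome, start, end and strand. Shares were given with Wilson 95% intervals, and a count of 0 with the share that 3 counts would make instead. Peaks of the lists were matched by an overlap of at least 1 base on the same strand. Overlap was taken over the genomic span from start to end, introns included. Introns were crossed by 16.9% of young and 22.5% of aged peaks. Genes were counted as shared, young-only or aged-only, which describes these lists and not gain or loss of methylation. A shared gene had a peak in both lists, and these peaks need not overlap. Members of 36 lists fixed before the data were examined were counted by gene name or deposited symbol, which matched 18 members to LOC genes, the first by name where several had the symbol. For the 26 lists with at least 5 members with a peak, the young-only and aged-only counts were placed among 10000 random lists from the genes with a peak, matched on merged peaks per gene in classes up to 3 or more. A percentile describes these lists and is not a test. Overlap and percentile code was tested on simulated data from the pool of 5261 genes, with lists of 20 genes and the young-only count. Of lists with 15 planted young-only genes, 100% were found, and 4% of random lists fell outside the central 95%. Smaller lists, weaker excesses and the aged-only count were not simulated, so a list within the limits can still differ.

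Named genes followed a rule set before the data were examined: the 10 highest folds among genes of each list only, leaving out LOC genes; the 5 genes with the most peaks per list; every m6A writer, eraser and reader with a peak; of each other list up to 4 genes of 1 list only by fold and up to 2 shared genes by number of peaks; and the 5 overlapping peaks with the highest lower fold. Some genes that the rule selects are not reported here. Alternatives were stricter folds (at least the median of 2.00 over both lists), an adjusted p of at most 0.01, equal list lengths, weighting by width, other overlap rules, exon and UTR labels only, and other matching. Chosen after seeing the data were the plus strand alone, peaks within 1 exon, equal lengths for feature shares, matching on whether a gene has a peak at its end, and leaving out LOC genes. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.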

Results

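N6-methyladenosine (m6A) is a methyl mark on internal adenosines of messenger RNA that is read by proteins acting on splicing, translation and decay. Ovaries of young sheep aged 1 to 2 years and of aged sheep aged 5 to 6 years were compared by immunoprecipitating RNA fragments with an antibody against m6A and sequencing them beside an untreated input library. The series had 4 samples, an immunoprecipitate and an input at each age, and 1 peak list per age was analysed here. A peak is a stretch of transcript enriched in the immunoprecipitate, and its fold enrichment, p-value and adjusted p-value are the authors' own. With 1 list per age, no difference between ages had a replicate check, no p-value was computed across ages, and 95% intervals of shares and of differences between shares cover counting error only. Sequencing depth was not given in the sources used here, and the input libraries were not used here, so the transcript abundance behind a peak is unknown.

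The young list held 4378 peaks in 3846 genes and the aged list 3656 peaks in 3086 genes. Most genes had a single peak, 87.9% of the young genes and 84.9% of the aged genes. TSHZ2, a zinc finger homeobox gene, had the most young peaks with 5, followed by ZNF462, MPZL1, the stress kinase gene MAPK14 and the chromatin remodelling gene RSF1 with 4 each. In the aged list the transcriptional repressor gene ZBTB7A, the non-muscle myosin gene MYH9 and XG had 5 peaks each, and the growth factor gene IGF2 and the splicing regulator gene NSRP1 had 4 each. IGF2 had 2 young peaks, and MYH9 had 1. Young peaks had a median fold of 2.05 and a median log10 p of -15.3, against 1.88 and -6.22 in the aged list. The aged list thus held weaker peaks by the authors' values, and 120 of them had an adjusted p above 0.05, against 10 young peaks.

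Most peaks at both ages were labelled stop codon or 3' UTR in the deposited annotation, in different proportions. Of the young peaks, 41.3% (39.8 to 42.7) were labelled stop codon and 47.3% (45.9 to 48.8) 3' UTR. Of the aged peaks, 15.3% (14.2 to 16.5) were labelled stop codon and 66.4% (64.8 to 67.9) 3' UTR. Among genes of the ovary, the young peak of STAR, whose product moves cholesterol into mitochondria for steroid synthesis, was labelled stop codon on chromosome 26 (32408293 to 32408590). The peaks of FSHR, the follicle-stimulating hormone receptor gene, were labelled stop codon at both ages. Labels of other features were less frequent, with exons at 9.30% of young and 15.3% of aged peaks, 5' UTRs at 1.55% and 2.49%, and start codons at 0.571% and 0.492%.

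The aged stop codon share depended on the strand of the gene. It was 27.5% of plus-strand peaks and 2.58% of minus-strand peaks, whereas the young shares were 43.1% and 39.0%. For the endothelial gene CLDN5 and the macrophage gene AIF1, both on the minus strand, the young peak was labelled stop codon and the aged peak 3' UTR. Among overlapping minus-strand pairs whose young label was stop codon, the aged label was 3' UTR in 221 and stop codon in 18. On the plus strand the corresponding numbers were 68 and 257. The stop codon label lay mostly at gene ends, except on the aged minus strand. Of young peaks so labelled, 70.8% ended at the last base of the gene in the gene table, as did 64.2% of aged plus-strand peaks and 0 of 46 aged minus-strand peaks, where 3 counts, the limit used for a count of 0, are 6.52%. Where a gene had peaks of both labels, the stop codon peak lay 3' of the 3' UTR peak in 209 of 223 young pairs. The same held for 75 of 82 aged plus-strand pairs and 5 of 14 aged minus-strand pairs. Of peaks ending at the last base of the gene, 1274 of 1280 young and 330 of 331 aged peaks were labelled stop codon. Peaks labelled 3' UTR ended there in 1 of 2060 young and 0 of 2416 aged cases, where 3 counts are 0.124%. Nearly all peaks that reached the last base thus carried the stop codon label. A stop codon lies 5' of the 3' UTR, so the label is not read here as the position of a stop codon. Standardised over classes of the deposited log10 p, the young share of stop codon labels on the plus strand was no longer higher (difference -3.42 percentage points, bootstrap 95% interval -7.03 to 0.545). The most significant of 10 classes held 400 young and 27 aged peaks, the least significant 37 and 390. The outer classes thus rest on few peaks of 1 list.

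**Figure D1:**
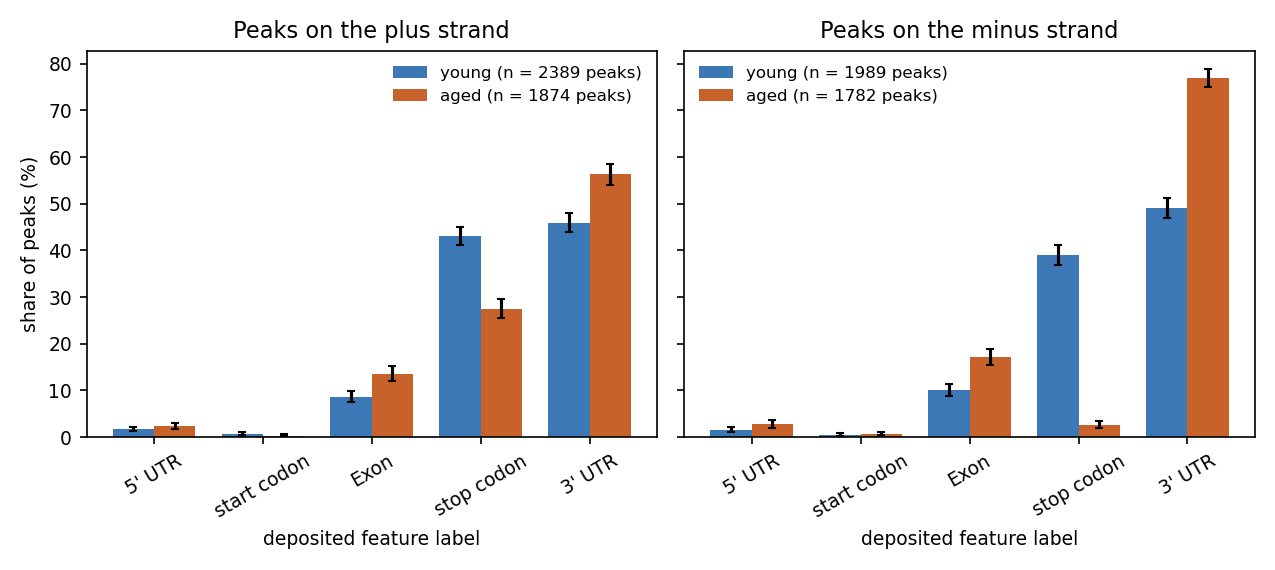
Share of peaks (%, y axis) with each deposited feature label (x axis), by strand and age; bars show 1 peak list each and error bars Wilson 95% intervals for counting error only. The aged stop codon share was 27.5% on the plus strand and 2.58% on the minus strand.

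**Figure D2:**
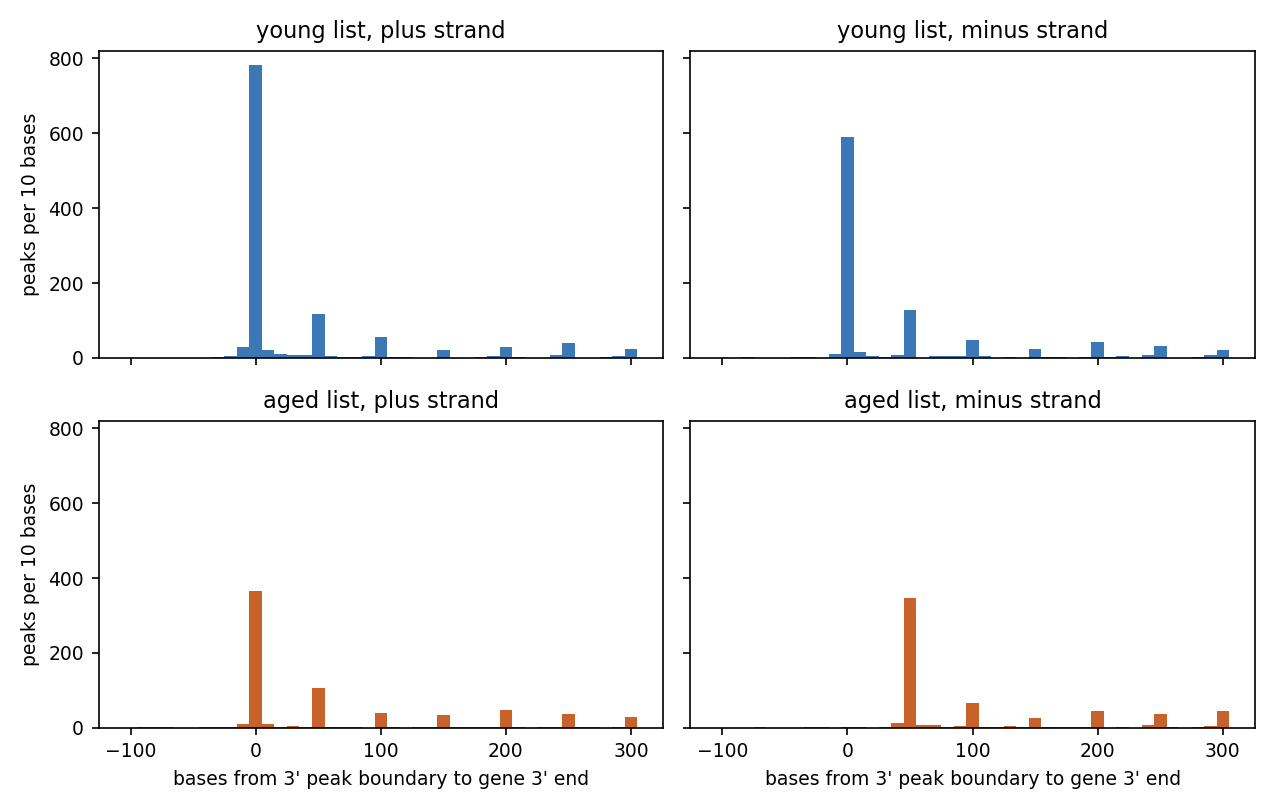
Number of peaks per 10 bases (y axis) by distance in bases from the 3' boundary of the peak to the 3' end of its gene (x axis), by age and strand, between -100 and 300 bases. Young and aged plus-strand peaks pile up at 0, and aged minus-strand peaks about 50 bases short of it, with 0 of 1772 exactly at the end.

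Peaks of 1 list overlapped the other list in a minority of cases. By at least 1 base on the same strand, 34.3% (32.9 to 35.8) of young peaks overlapped an aged peak and 41.0% (39.4 to 42.6) of aged peaks overlapped a young one. In genes with a peak at both ages the shares were 74.2% and 72.2%, and 146 peaks had identical boundaries. Overlapping peaks were ranked by the lower of their young and aged folds. The leading one lay in LZIC, with a 3' UTR label on chromosome 12 (42875556 to 42875705). Its folds were 4.67 in the young and 4.80 in the aged list. Peaks in MEGF6 (4.57 and 3.83) and ZNF783 (4.80 and 3.69) came next. NSRP1 (3.60 and 4.40) and PRRC2C (3.30 and 3.56) followed, each with a peak labelled exon. Requiring 50% of both peaks lowered the shares to 24.3% and 29.0%. Spans included introns, and with only peaks within 1 exon the shares by 1 base were 31.2% and 40.1%.

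Of 5261 genes with a peak, 1671 (31.8%) had one at both ages, 2175 (41.3%) in the young list only and 1415 (26.9%) in the aged list only. The young-only genes with the highest folds were the tubulin deglutamylase gene AGBL5 (6.60), the dynein light chain gene DYNLL2 (6.50), STEEP1 (6.33), the transcription factor gene CEBPB (6.00) and the cholesterol exporter gene ABCA1 (5.33). The prostacyclin synthase gene PTGIS (5.29), the dynein gene DNAH3 (5.20), ARHGEF37 (5.20), the ribosome biogenesis gene RRS1 (5.00) and PIN4 (5.00) completed the leading 10. The ABCA1 peak was labelled stop codon on chromosome 2 (18233803 to 18234003), and that of CEBPB 3' UTR on chromosome 13 (78228550 to 78228746). The aged-only genes with the highest folds were the centrosomal gene WDR62 (8.00), LRRC4C (6.67), the catenin gene CTNND2 (5.75), C12H1orf159 (5.37) and the fatty acid activating enzyme gene ACSL5 (5.12). TNIK (5.00), SH3KBP1 (5.00), the deubiquitinase gene OTULIN (4.87), BVES (4.67) and the defensin gene DEFB124 (4.67, adjusted p 0.10) completed the 10. The WDR62 peak was labelled stop codon on chromosome 14 (46071699 to 46071849). With only peaks labelled exon or UTR the balance turned, to 32.4% young-only and 41.3% aged-only genes. This setting leaves out all peaks labelled stop codon, 41.3% of the young but 15.3% of the aged list. In 289 overlapping pairs the young label was stop codon and the aged label 3' UTR, against 48 pairs the other way round. The turn may thus follow from the labels.

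Genes of the m6A machinery carried peaks themselves. METTL14, part of the methyltransferase core, and CBLL1, a subunit of the writer complex, had peaks at both ages, CBLL1 with folds of 2.94 and 2.66. METTL3, the catalytic subunit, and VIRMA, a scaffold of the complex, had a peak in the young list only (1.83 and 2.56). METTL16, which methylates U6 RNA, had 4 peaks in the aged list only, and ZC3H13 had 1 aged peak with an adjusted p of 0.545. The demethylase gene ALKBH5 (2.50) and the reader genes YTHDF1 (1.62), HNRNPA2B1 (3.25), RBMX (3.33) and FMR1 (2.33) had peaks in the young list only. No peak was found in either list for 10 of 14 readers, 4 of 10 writers and 1 of 2 erasers. Of all genes with a peak, 41.3% were young-only, and these lists are too small to set against that share.

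Of 8 genes for gonadotropin, oestrogen and progesterone signalling with a peak, 7 were young-only and 1, FSHR, was shared. The young-only members included the cAMP-degrading phosphodiesterase gene PDE4D (3.75), PGRMC2 (2.82), the prostaglandin F receptor gene PTGFR (1.83) and PRKAR2B (1.67), a protein kinase A subunit gene. That count lay at percentile 98.7 of 10000 random gene lists matched on peaks per gene. It fell below the limit of 97.5 with lists of equal length (97.1), without LOC genes (97.4) and on the plus strand alone (94.6). With stricter folds only 3 of these genes kept a peak, 2 young-only and 1 aged-only. Steroid synthesis and transport had 4 young-only, 3 aged-only and 6 shared genes, and with stricter folds 3 young-only and 1 shared. STAR (2.75) and FDXR (1.59) were young-only and SRD5A1, a steroid 5-alpha reductase gene, aged-only (1.85), while FDX1 and the cholesterol esterifying gene SOAT1 were shared.

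For energy and translation genes the excess of young-only genes depended on the setting. Of 12 oxidative phosphorylation genes with a peak, 10 were young-only, among them ATP5PO (2.70) and NDUFV2 (2.00), subunit genes of ATP synthase and complex I, and 2 were aged-only (percentile 99.25). Of the 10, 5 were LOC genes matched by their deposited symbol, which can be copies of the named gene and are uncertain; without LOC genes the percentile was 88.6, and with equal list lengths 96.0. Cytosolic ribosomal protein genes were 11 young-only, 4 shared and 2 aged-only (93.9), with RPL27 young-only (1.95), and both aged-only members were LOC genes. That percentile was 99.6 without LOC genes, but 83.5 when matched on gene length.

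Histone and DNA modifier genes had peaks more often in the aged list only than in random lists. Of 24 histone and DNA modifier genes with a peak, 12 were aged-only, 7 young-only and 5 shared, and the aged-only count lay at percentile 99.7. HDAC9 (2.67), a histone deacetylase gene, and SETD5 (2.33) were aged-only. The demethylase genes KDM4B (3.50) and KDM5B (2.60) were young-only, and the DNA methyltransferase gene DNMT3A and NSD1 were shared. The young and aged peaks of DNMT3A did not overlap. With stricter folds the percentile was 94.3, and matched on gene-end peaks 96.25. NOTCH signalling had 5 aged-only, 2 young-only and 1 shared gene (97.4, and 98.1 with the stricter adjusted p), but 1 aged-only and 2 young-only genes with stricter folds, with NOTCH4 (2.14) and NOTCH2 (1.68) aged-only, RBPJ (2.36), which encodes the DNA-binding partner of NOTCH, young-only, and the target HES1 shared.

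Growth and differentiation pathways were mixed. TGF-beta, BMP and activin signalling had 8 of 12 genes in both lists, including INHBB and SMAD2, but with stricter folds 2 of 8, with 5 young-only. The inhibin subunit gene INHBA (2.67) and TGFB2 (2.67) were young-only, and SMURF1 (2.00) and SMAD3 (1.64) aged-only. In PI3K, AKT, FOXO and mTOR signalling 9 of 18 genes were shared (4 of 12 with stricter folds), including IGF1 and TSC1, 6 were aged-only, including IRS1 (2.33), and 3 were young-only, including PRKAA1 (2.60) and EIF4EBP1 (2.25). Hippo signalling had 5 young-only genes, among them FAT4 (2.67), LATS1 (2.40), VGLL4 (2.04) and CCN1 (1.80), 4 shared ones, including LATS2 and AMOTL1, and no aged-only gene. WNT signalling had 8 young-only genes, including GSK3B (2.75), DVL1 (2.40) and SFRP1 (2.30), 4 aged-only, including LEF1 (2.50, adjusted p 0.0832), and 4 shared, including FZD4 and TCF7. With matching on peaks per gene, these 4 lists lay between percentiles 2.5 and 97.5. Unmatched, the young-only count of the PI3K list lay at 1.60 (1.90 matched on gene-end peaks), and matched on gene length the aged-only count of the Hippo list lay at 2.20.

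Lists for ageing, repair and matrix were mixed as well. DNA repair had 7 young-only, 6 aged-only and 6 shared genes, with WRN (3.14), BRCA1 (2.50) and CHEK2 (2.15) young-only and ERCC5 shared. The cell cycle had 6 young-only genes, including CCND2 (3.07) and CDK6 (2.71), 4 aged-only, including the proliferation marker MKI67 (3.71) and CDC25A (2.92), and MCM6 shared. Among senescence genes SIRT6 (1.75) and HMGA1 (1.55) were young-only, LMNB1 (2.03) aged-only, and CDKN1B and ETS1 shared. Of secreted factors of senescent cells, VEGFA (1.75), STC1 (1.65) and IGFBP5 (1.53) were aged-only, CXCL12 (1.67) young-only, and TIMP2 and IGFBP3 shared. Antioxidant genes with a peak numbered 5, with the stress regulator NFE2L2 (1.75) and GCLM (1.64) aged-only, PRDX4 (1.69) young-only, and KEAP1 and GSTA1 shared. Of apoptosis genes, CASP9 (2.67), FADD (2.14) and BCL2L1 (1.57) were aged-only, MCL1 (2.47) young-only and BIRC2 shared. Autophagy had 7 young-only genes, including MAP1LC3B (2.80), RB1CC1 (2.33) and LAMP2 (2.00), 4 aged-only, including ATG14 (2.11), and 4 shared, including OPTN and NBR1. Extracellular matrix genes were 9 shared, 7 young-only and 6 aged-only, with the collagen genes COL1A2 (2.40), COL6A1 (2.40) and COL6A2 (2.29) young-only, THBS1 (2.71) aged-only, and COL1A1 and ADAMTS1 shared. Angiogenesis genes were 8 shared, 7 young-only and 7 aged-only, with ANGPT1 (3.00) and EPAS1 (2.37) young-only, EGLN1 (2.60) aged-only, and FGF1 and PDGFA shared. With the lists as deposited, these 9 lists lay between percentiles 2.5 and 97.5. At equal list lengths the aged-only count of the apoptosis list lay at 98.3. With stricter folds the shared genes fell to 1 of 11 for extracellular matrix, 2 of 13 for angiogenesis and 0 of 5 for DNA repair, and apoptosis had 2 young-only and 2 aged-only genes.

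Markers of ovarian cell types showed which transcripts were covered. Of 8 oocyte genes with a peak, 5 were aged-only, including the oocyte transcription factor gene NOBOX (2.85, adjusted p 0.0245), NLRP14 (2.75) and PADI6 (2.06), FIGLA (2.55) was among 2 young-only, and NPM2 was shared; the aged-only percentile was 96.7, and 97.8 matched on gene length. Of 5 granulosa genes, 4 were shared, including FSHR and INHBB, and INHBA was young-only, but with stricter folds none of 4 was shared and 3 were young-only. Theca and luteal genes were 3 young-only, STAR, PTGFR and CYP17A1 (1.56), 1 aged-only, SCARB1 (1.55), and 1 shared, FDX1. Of 9 stromal fibroblast genes, 6 were young-only, including DPT (3.60) and NR2F2 (2.67), and 2, COL1A1 and PDGFRL, were shared; the young-only percentile of 97.6 fell below the limit in most other settings, to 79.8 with equal list lengths. Endothelial genes were 3 young-only, including FLT1 (1.94) and EGFL7 (1.82), 3 aged-only, including KDR (2.13) and PECAM1 (1.78), and 2 shared, CLDN5 and ERG. The young and aged peaks of ERG did not overlap. Macrophage genes were 4 young-only, including MSR1 (2.00), C1QB (1.64) and CD68 (1.60), and 2 shared, AIF1 and CD86. Fewer than 5 genes had a peak for smooth muscle (DES and LMOD1 young-only, PDGFRB and CSPG4 shared), lymphatic endothelium (CCL21 young-only, LYVE1 aged-only, FLT4 shared) and surface epithelium (KRT7 and UPK3B young-only, KRT19 aged-only, KRT18 shared). CD2 of T cells and NCAM1 of neural cells were aged-only, JCHAIN of plasma cells was young-only, and no mast cell or erythroid gene had a peak.

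**Figure D3:**
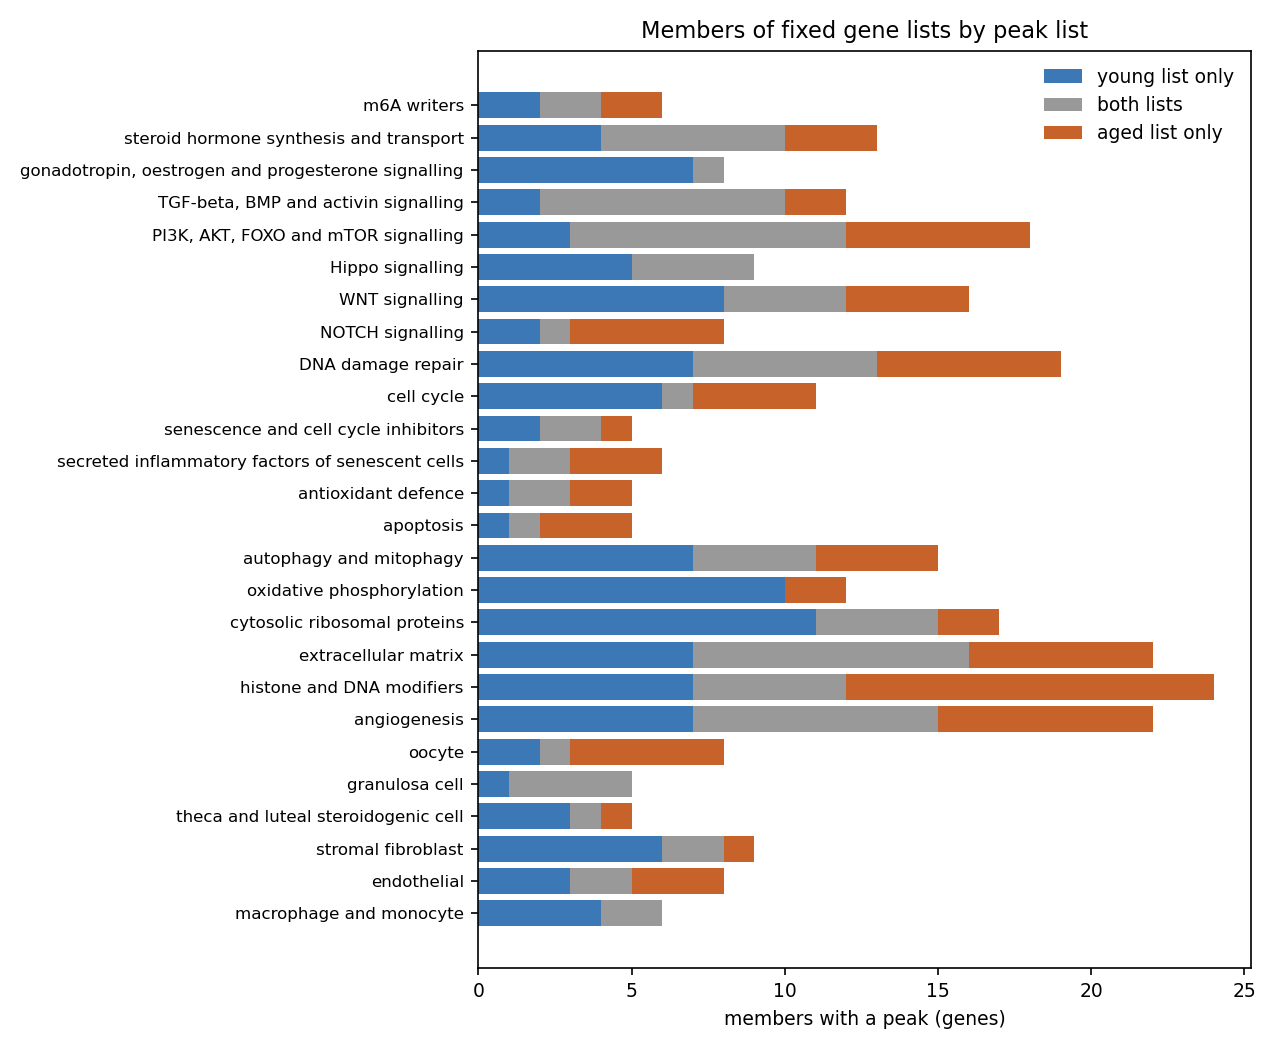
Number of member genes with a peak (x axis) in the young list only, both lists or the aged list only, for each fixed list with at least 5 such members (y axis). Young-only genes made up 10 of 12 for oxidative phosphorylation, and aged-only genes 12 of 24 for histone and DNA modifiers.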

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

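The gene end comparison, the strand comparison and the gene length test below were chosen after the results were seen; the tests on peak significance, LOC genes and equal list lengths of deposited terms were set before their results were seen, although LOC genes and equal lengths had by then been examined for the related fixed lists. The strand of a peak and its distance to the gene end entered no planned comparison. Peaks ended exactly at the gene end in 30.7% of young plus-strand, 27.9% of young minus-strand and 17.7% of aged plus-strand peaks, whereas over both strands 8 young and 4 aged peaks ended 1 base from it. On the aged minus strand 0 of 1772 peaks did, where 3 counts, the limit used for a count of 0, are 0.169%, and 17.2% ended 49 or 50 bases short.

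For the aged strand gap in the stop codon label, 24.9 percentage points, a candidate explanation is that the last bin of minus-strand genes is missing from that list. Allowing 60 bases, the strand gap was 6.30 points (3.52 to 9.06), so most of the label gap may come from this boundary, as for CLDN5 and AIF1. The cause of the missing bin and of the remaining gap was not tested.

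The lower aged stop codon share is not explained by that boundary alone, since on the plus strand the young share was still 15.6 points higher (12.8 to 18.4, counting error only). The other technical explanation was peak significance, because stop codon labels were more frequent among more significant peaks at both ages. By fold the 2 lists went opposite ways. Median folds of stop codon and 3' UTR labels were 2.00 and 2.12 in the young list, and 1.94 and 1.87 in the aged list. Standardised over 10 classes of the deposited log10 p, the plus-strand difference was -3.42 points (-7.03 to 0.545), and the young share was higher in 3 of 10 classes. The lists overlapped little in significance: the most significant class held 400 young and 27 aged peaks, the least significant 37 and 390. The outer classes thus rest on few peaks of 1 list. With that limit, the difference in labels may come from the different significance of the lists. An effect of age on peak significance stays open and untested with 1 list per age.

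In a screen of 133 deposited pathway terms, from which both were picked after their values were seen, the terms placed oxidative phosphorylation (27 of 36 genes young-only) and ribosome (42 of 62) on the young side. For these terms, gene length as the whole cause is argued against by percentiles of 99.97 and 99.5 among lists matched on length. Copies under LOC names are argued against by 99.7 and 99.85 without them, and the weaker peaks of the longer young list by 99.9 and 99.9 at equal list lengths. The young peaks kept there had a log10 adjusted p of at most -9.54, against an aged median of -5.40. The lists thus stayed unequal, and weaker detection in the aged list was not tested. The fixed lists were less firm, with oxidative phosphorylation at 88.6 without LOC genes and 96.0 at equal lengths, and ribosomal proteins at 83.5 when matched on gene length, so that length stays open for the latter. Transcript abundance, which the inputs measure and which was not analysed here, and age itself stay open as candidate explanations.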

How the results depend on the processing

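The plus strand alone, peaks within 1 exon, equal lengths for label shares, matching on gene-end peaks and leaving out LOC genes were chosen after the data were seen. Stricter folds left 2553 young and 1562 aged peaks in 2333 and 1430 genes, labels of 36.1% stop codon and 51.3% 3' UTR in the young list, overlaps of 20.2% of young and 32.8% of aged peaks, 19.1% shared and 54.7% young-only genes. Against all peaks of the other list, 54.5% of strict young and 39.4% of strict aged genes had no counterpart. With an adjusted p of at most 0.01, overlap was 32.7% of young peaks, with 43.8% young-only and 25.4% aged-only genes. With equal list lengths the young list had 44.8% stop codon and 45.0% 3' UTR labels, overlaps were 36.2% and 36.2%, and genes were 30.1% shared, 37.3% young-only and 32.6% aged-only. Weighted by width, young 3' UTR labels made up 45.8%. Overlap of 50% of the shorter peak gave 31.9% and 38.1%, and of both peaks 24.3% and 29.0%. With exon and UTR labels only, genes were 26.3% shared, 32.4% young-only and 41.3% aged-only. On the plus strand, stop codon labels were 43.1% young and 27.5% aged, aged 3' UTR labels 56.35%, aged overlap 43.5%, and genes 42.8% young-only and 25.0% aged-only. Within 1 exon, labels were 43.2% stop codon and 51.8% 3' UTR in the young and 75.0% 3' UTR in the aged list, young overlap 31.2%, and genes 28.9% shared and 44.6% young-only. The young stop codon share exceeded the aged one with stricter folds, the stricter adjusted p, equal lengths, weighting by width, the plus strand alone and peaks within 1 exon, but not on the plus strand when standardised over classes of the deposited log10 p (-3.42 points, -7.03 to 0.545). Among these gene counts, young-only genes outnumbered aged-only genes except with exon and UTR labels only. That setting drops a larger share of the young than of the aged peaks.

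Young minus aged peak numbers turned for ETS1 (-1) at equal lengths, for FANCA (1) and NSD1 (1) with the stricter adjusted p, and for NSRP1 (2), SMAD2 (1) and XG (2) with stricter folds; the cause was not tested beyond the loss of weaker peaks. Of 130 named genes of 1 list only, 94 stayed in that list alone with stricter folds and 36 had no peak left. Among list percentiles 343 kept their side of the limits, 13 lost it and 12 passed it. No paired analysis was possible because there was 1 list per age, and leaving out a replicate was not possible either. Shuffled motifs and an independent annotation were not run.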

Other observations

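The screens of this part were chosen after the data were seen. Zinc finger protein genes, many of which encode DNA-binding repressors, lay on the aged side: of 167 with a peak, 64 were aged-only, 50 young-only and 53 shared, against 42.8 aged-only genes in random lists. Spliceosome genes lay on the young side, with 34 of 58 young-only against 23.5 in random lists. Thyroid hormone signalling had 24 of 43 genes aged-only against 11.3, and the insulin signalling term 21 of 53 against 13.7, at percentile 98.8 and, matched on gene length, 96.6. The ATP-dependent chromatin remodeling term had 11 of 42 genes aged-only against 11.6.

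Of 133 deposited pathway terms with at least 30 genes, 12 lay above percentile 97.5 for young-only genes and 14 for aged-only genes, where 3.325 were expected by chance on each side if terms were independent. Terms share genes, so these are not separate findings. Several terms differed from the fixed list nearest to them. Estrogen signaling had 15 young-only and 15 aged-only genes of 41, and GnRH signaling 13 young-only and 9 aged-only of 31. Wnt signaling had 22 young-only and 22 aged-only genes of 59, with an aged-only percentile of 97.7, and 92.1 matched on gene length. Cellular senescence had 30 of 58 genes young-only (97.9, and 95.8 matched on length). The Prion disease term, which holds many respiratory chain genes, had 52 of 79 genes young-only.

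A fold of exactly 2.00 was given for 313 young and 191 aged peaks, against 3 and 5 at the next lower value of the column. The X chromosome carried 3.06% of young and 2.98% of aged peaks.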
